A study of Caenorhabditis elegans with 2 samples.

How the data were processed

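Binding sites of NHR-76, a nuclear hormone receptor of the nematode Caenorhabditis elegans, were measured by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in mixed-stage embryos. Per the labels, the worms carried a transgene that expresses NHR-76 with GFP and FLAG tags at its C terminus, chromatin was sheared by sonication, and the 2 libraries are biological replicates 1 and 2 of 1 group. No second condition was analysed here.

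The authors deposited peak lists for 2 genome assemblies, ce11 and ce10. Per the deposited README files, 1 list of peaks and background was made from the alignment of each replicate against a control alignment, and 1 from the pooled alignments of both replicates. These lists were the input of the irreproducible discovery rate (IDR) procedure, which weighs how far the ranks of peaks repeat. The optimal IDR-thresholded list was derived from them. Not every peak on that list was also listed in replicate 1. The pooled list is called the candidates below, and the thresholded list the final peaks. The aligner, the peak caller and its version, and the IDR threshold are not given in the sources used here. Column 7 of each list holds the authors' signal value per peak, whose scale is not stated. Column 9 holds the −log10 of the q-value as the narrowPeak format of the deposited lists defines it, and 725 of the pooled candidates share its highest value. Columns 5 and 8 hold the single values 0 and -1 throughout. Signal values are the authors' own and were used only to describe and rank peaks within a list. Read numbers are not part of these lists, so the sequencing depth behind them is unknown. Intervals on shares are exact Clopper-Pearson intervals at the 95% level and cover counting error over peaks only.

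The main results use ce11 coordinates, given from 1, with the Ensembl release 115 annotation and the RefSeq sequence of WBcel235, the same assembly as ce11. All peak ends lay within the lengths of its 7 sequences. Names of mitochondrial protein-coding genes came from RefSeq genes at the same positions. No annotation of ce10 was used here, so ce10 entered only counts of peaks, chromosomes and signal values, and no coordinates were converted.

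A final peak was placed by its summit. Location was the share of summits within 500 bp of an annotated protein-coding transcript 5′ end, and other summits were sorted into 5′ UTR, coding exon, 3′ UTR, intron and intergenic, in that order. Final peaks were compared with the other pooled candidates, those that overlap no final peak, by Fisher's exact test, two-sided. The chromosome test was a seeded permutation chi-square with 100000 draws. For 24 gene lists, protein-coding genes nearest to a final peak within 1000 bp were compared with all genes nearest to a candidate under the same rule. For 8 noncoding biotypes, summits within 500 bp of such a gene were counted. The reason set in advance was that RNA polymerase III and other highly transcribed loci are common nonspecific ChIP signals in worm. For 17 sequence motifs, windows of 100 bp on each side of the summit were searched on both strands, against 5 candidates per peak matched on promoter class and on GC content in steps of 5 percentage points. P-values were adjusted by Benjamini-Hochberg within each family, with a threshold of 0.05. Replicate support counted final peaks that overlap, by 1 bp or more, any listed peak of a replicate or 1 of its top 140 peaks by signal. Random draws from the same lists were planned as its comparison and are not reported, because the final peaks derive from the same alignments and must exceed them. Rank agreement was Spearman's rho over candidates with a summit within 100 bp of a summit in both replicate lists. Peaks are not independent replicates, so no p-value is attached to it.

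The designs, lists, motifs and main alternatives were fixed before the data were examined. Named peaks are the 25 final peaks with the highest signal, each called by the protein-coding gene with the nearest 5′ end, up to 5 genes per list near a final peak, and nhr-76, unc-119 and atgl-1 in any case. Other genes named were chosen after their values were seen, and the text says so. Alternatives were 1 replicate alone (its top 140 peaks against the rest of its own list), the 70 final peaks with the higher signal, other distances, windows, backgrounds and overlap rules, and the other assembly. Alternatives without mitochondrial peaks, without mitochondrial peaks and 1 replicate, without tRNA and snoRNA peaks, with the next 140 candidates as background of the noncoding test, with the next 122 nuclear candidates against the nuclear peaks, and with 10 biotypes were chosen after seeing the data. The rest of a replicate's own list as background was not fixed in advance.

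The tests of location, chromosomes, gene lists, noncoding genes and motifs were run on simulated data, 40 sets of 140 candidates drawn at random and 40 with a known excess. At least 1 call was made in 3 of the 40 random sets for location, 1 for chromosomes, 3 for gene lists, 0 for noncoding genes and 3 for motifs. The planted excess was called in 40 of 40 sets in each of these tests. The location sets held 70 peaks near a 5′ end in total, so their excess over random candidates was smaller than 70. The other sets held planted peaks beside randomly drawn ones, 70 for chromosomes, 10 for gene lists, 20 for noncoding genes and 28 for motifs. Rank agreement of 1 pair of simulated lists made with a rho of 0.4 came out at 0.362 over 2000 peaks. The replicate support counts, the word search and the rotation test were not simulated. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and bedtools 2.31.1 were used, with seed 7.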

Results

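NHR-76 binding was profiled in C. elegans embryos of mixed stages, in 2 biological replicates of 1 strain that expresses the receptor with GFP and FLAG tags. NHR-76 belongs to the nuclear hormone receptors and is known for its part in fat regulation in the intestine, where it acts on the lipase gene atgl-1. The replicate lists held 7516 peaks for replicate 1 and 30000 for replicate 2, and the pooled list held 30000 candidates. The sequencing depth is unknown, so the lists' lengths cannot be related to read numbers. With 1 group only, the comparisons below are between final peaks and other candidates and between the replicates.

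The 4 strongest nuclear peaks lay just upstream of atx-2, ears-2, idhg-1 and B0495.9. The highest, with a signal of 107, was on chromosome III at 10461238 to 10461419 (ce11), 47 bp upstream of the 5′ end of atx-2, the worm ataxin-2 gene. Next came ears-2, a glutamyl-tRNA synthetase gene, with a signal of 82.8 on chromosome IV at 390408 to 390577, 28 bp upstream, and idhg-1, a subunit of isocitrate dehydrogenase, with 68.1 on chromosome III at 4568686 to 4568816, 46 bp upstream. B0495.9 followed with 61.0 on chromosome II at 7708697 to 7708828. The peaks at atx-2 and ears-2 ranked 7 and 13 in replicate 1, and 3 and 5 in replicate 2. The idhg-1 peak ranked 12 and 11.

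The other nuclear members of the 25 strongest peaks had signals between 43.9 and 56.5. Those at dnj-29 (a DnaJ-type chaperone gene, 56.5), K05C4.7 (53.0), C46F11.4 (51.7), spe-48 (51.1), tasp-1 (47.7), K05C4.2 (45.6), tre-1 (a trehalase gene, 45.4) and ccdc-47 (43.9) all had their summit upstream of the 5′ end, within 500 bp. The exception was the peak of signal 47.9 on chromosome V at 8500420 to 8500759, 5701 bp downstream of the 5′ end of pxn-1, a peroxidasin gene. It lay in an intron of pxn-1, on the snoRNA gene ZK994.7. Of the 13 nuclear peaks among the 25 strongest, 12 were within 500 bp of a protein-coding 5′ end.

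The other 12 of the 25 strongest peaks were in the mitochondrial genome. The strongest peak of all, with a signal of 442, lay in the coding sequence of ND5 at 12325 to 12629, and the next, with 148, in that of COX3 at 5848 to 6187. Further mitochondrial peaks lay in ND4 (79.8, nearest to the 5′ end of COX1), in COX1 (64.7 and 59.9), upstream of ND3 (64.1), in ATP6 (60.2, nearest to ND2), in ND6 (51.7), on a ribosomal RNA gene next to ND4L (49.8) and upstream of ND1 (46.5), in ND5 again (47) and in CYTB (42.6). The ND5 peak ranked first in both replicates.

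The final set held 140 peaks in ce11, of which 18 (12.9%, interval 7.80% to 19.6%) were mitochondrial and 122 nuclear. They were exactly the 140 candidates with the highest signal in the pooled list, with values from 20 to 442 and a median of 25.6. Widths were 340 bp in 133 peaks and narrower in 7. Together they covered 46114 bp in 137 merged regions. The ce10 final set held 145 peaks, 17 of them mitochondrial, with a median signal of 25.2.

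**Figure D1:**
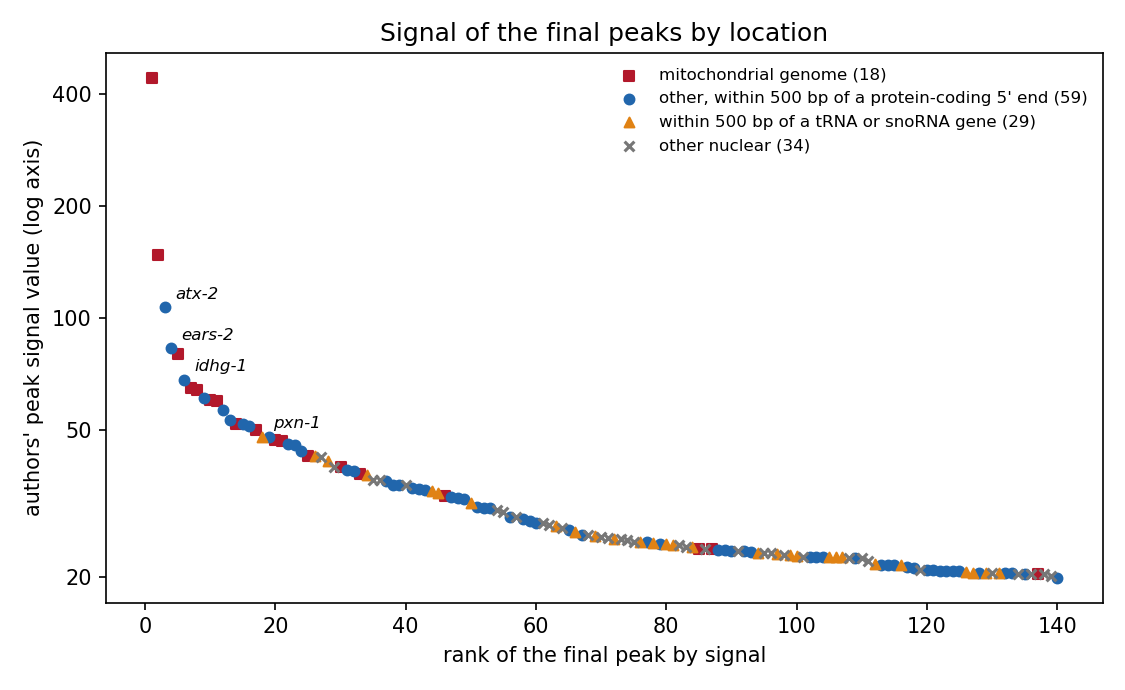
Authors' signal value (log axis) of the 140 final peaks against their rank by signal, with 1 point per peak. Squares are the 18 mitochondrial peaks, triangles the 29 nuclear peaks within 500 bp of a tRNA or snoRNA gene, circles the 59 other nuclear peaks within 500 bp of a protein-coding 5′ end, and crosses the 34 remaining nuclear peaks. The strongest peak, in ND5, stands at 442, and atx-2 leads the nuclear peaks at 107.

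How far each replicate alone held the final peaks was asked next. Replicate 2 listed a peak at 140 of the 140 final peaks and replicate 1 at 129 (92.1%, interval 86.4% to 96.0%). Among the top 140 peaks of each replicate, replicate 2 covered 109 final peaks (77.9%, interval 70.1% to 84.4%) and replicate 1 covered 64 (45.7%, interval 37.3% to 54.3%). The top peaks of replicate 2 alone covered 60 final peaks, and those of replicate 1 alone 15.

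The top peaks of both replicates covered 49 final peaks (35.0%, interval 27.1% to 43.5%) and the top peaks of neither covered 16. Among the 70 final peaks with the higher signal the share covered by both was 65.7%. Of the top 140 peaks of replicate 1, 52 (37.1%, interval 29.1% to 45.7%) overlapped the top 140 of replicate 2, 17 of them mitochondrial and 35 nuclear. Across 1072 candidates matched in both lists, the signals correlated with a Spearman rho of 0.38, and of 0.21 across the 963 left without the final peaks. By chromosome the rho ran from 0.20 on chromosome II to 0.46 on chromosome III (SD 0.0904 over 6 nuclear chromosomes). These values are across peaks, which are not independent.

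**Figure D2:**
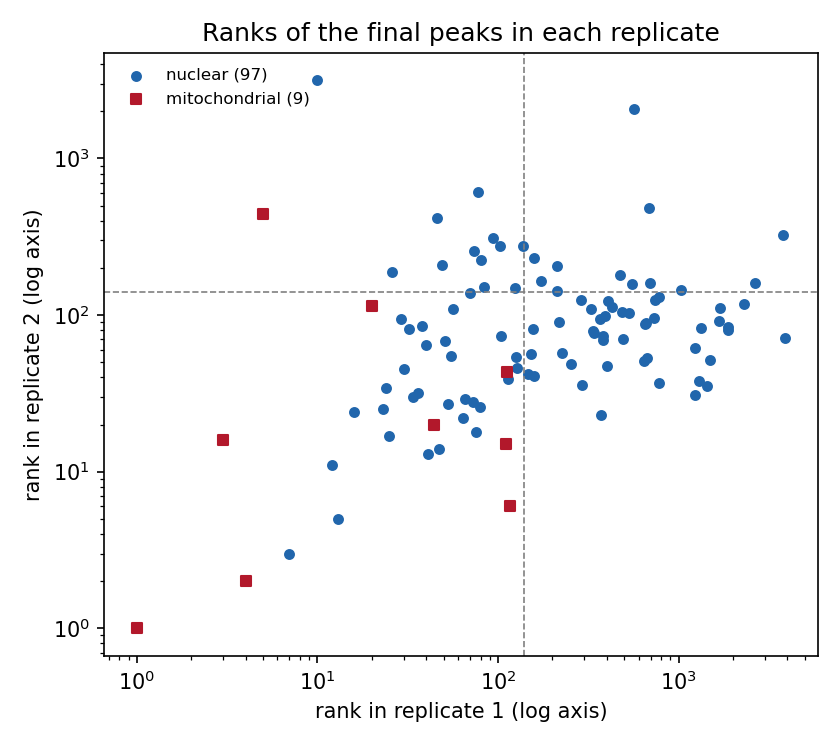
Rank in replicate 2 (vertical axis) against rank in replicate 1 (horizontal axis), both on log axes, for the 106 final peaks with a summit within 100 bp of a listed summit in both replicates, 97 nuclear and 9 mitochondrial. Dashed lines mark rank 140 in each list. Many points lie to the right of the vertical line and below the horizontal one. Counted by overlap over all 140 final peaks, which is another rule and set, 60 were covered by the top peaks of replicate 2 alone.

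Final peaks lay at promoters more often than candidates in general. Of the 140, 80 (57.1%, interval 48.5% to 65.5%) had their summit within 500 bp of a protein-coding 5′ end, against 27.7% of 29846 other candidates (odds ratio 3.48, Fisher's exact test, two-sided, p = 3.85e-13). Random positions on the same chromosomes gave 29.5% (odds ratio 3.19, same exact test, p = 1.39e-10). These positions followed the chromosomes of the final peaks, 18 of which were mitochondrial, while the other candidates were almost all nuclear. Their share therefore cannot say whether the other candidates, a list of peaks and background, lay closer to promoters than random positions. Among the 68 nuclear peaks at promoters, 61 had their summit upstream of the 5′ end and 7 downstream, at a median distance of 176 bp. Coding exons held 5 final peaks (3.57%), of which 1 was nuclear, against 21.5% of the other candidates, which are nuclear but for 1. Introns held 24, intergenic sequence 31, and 3′ UTRs 0 (interval 0% to 2.60%).

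The next-strongest candidates also lay often at promoters. Against the next 140 candidates by signal, of which 47.9% were within 500 bp of a 5′ end, the difference did not pass (odds ratio 1.45, Fisher's exact test, two-sided, p = 0.151). On nuclear peaks alone, a choice made after seeing the data, the shares were 55.7% and 45.9% of 122 each (odds ratio 1.48, exact test, p = 0.159).

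**Figure D3:**
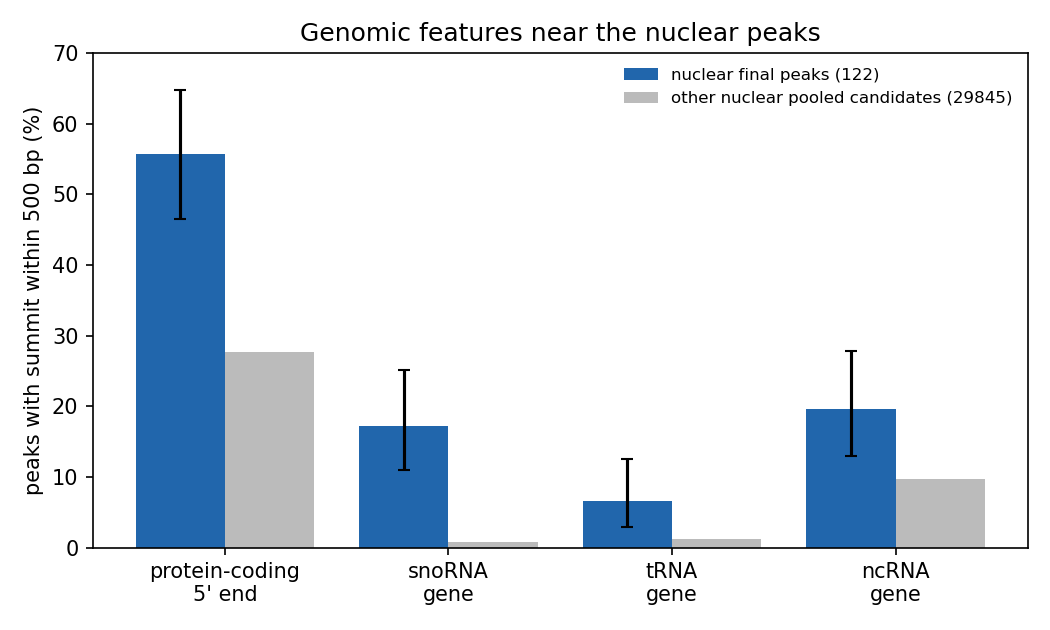
Share of the 122 nuclear final peaks and of the 29845 other nuclear candidates with their summit within 500 bp of a protein-coding 5′ end, a snoRNA gene, a tRNA gene or an ncRNA gene. Bars start at 0, and lines are exact 95% intervals of the final peaks' shares. The widest relative gap is at snoRNA genes, 17.2% against 0.744%.

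Genes for small noncoding RNAs were the other frequent sites. Whether the peaks there reflect NHR-76 or nonspecific signal was not tested. A snoRNA gene lay within 500 bp of 21 final peaks (15%, interval 9.53% to 22%), against 0.744% of the other candidates (odds ratio 23.5, Fisher's exact test, two-sided, p = 1.02e-20, adjusted p = 8.12e-20 over 8 biotypes), and within 100 bp of 20 of them. Without replicate 2 the share was 7.86% and the odds ratio 7.85, still past the threshold (adjusted p = 2.05e-06, exact test). Besides ZK994.7 in pxn-1, the strongest of these were at C51F7.4, inside frm-7 (signal 42.4), and at T03F7.8, inside cutl-18 (41.1), both chosen after their values were seen. A tRNA gene lay near 20 final peaks (14.3%, interval 8.95% to 21.2%) against 1.15% (odds ratio 14.3, exact test, p = 6.31e-16, adjusted p = 2.52e-15), but 12 of the 20 were mitochondrial. Without replicate 2 the tRNA share was 11.4% and the odds ratio 9.26 (adjusted p = 3.01e-09, exact test). Among the 122 nuclear peaks the tRNA share was 6.56% (8 peaks, odds ratio 6.04, exact test, p = 9.89e-05, adjusted p = 0.000395). This nuclear call was lost without replicate 2, with 4 of the nuclear top peaks of replicate 1 near a tRNA gene (3.36%, odds ratio 2.52, exact test, p = 0.0839, adjusted p = 0.134), a choice made after seeing the data. In all, 29 nuclear peaks (23.8%, interval 16.5% to 32.3%) were near a tRNA or snoRNA gene, and 9 of these were also within 500 bp of a protein-coding 5′ end.

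Among the other biotypes, rRNA genes were near 6 final peaks, all mitochondrial (4.29% against 0.0101%, exact test, p = 7.72e-13, adjusted p = 2.06e-12). The other candidates held 1 mitochondrial peak, so this call cannot be told apart from the excess of mitochondrial peaks in the final set. Of the 122 nuclear final peaks, 0 were near an rRNA gene. Genes annotated as ncRNA were near 24 (17.1% against 9.75%, exact test, p = 0.00621, adjusted p = 0.0124) and miRNA genes near 3 (2.14% against 0.338%, p = 0.0129, adjusted p = 0.0206). The piRNA genes were near 0 (interval 0% to 2.60%) against 3.44% (exact test, p = 0.0164, adjusted p = 0.0219). The snRNA genes (1 peak, adjusted p = 0.221, exact test) and pseudogenes (2 peaks, adjusted p = 0.247) did not pass. The ncRNA, miRNA and piRNA calls were lost without replicate 2, with adjusted p of 0.0523, 0.166 and 0.0523 by the same exact test, and among the 70 stronger peaks. Without replicate 2 the ncRNA share was 16.4% (odds ratio 1.66) and the piRNA share 0%, both near their values with both replicates, while the miRNA odds ratio fell from 6.45 to 3.12. On nuclear peaks without replicate 2, a choice made after seeing the data, the ncRNA excess passed (19.3%, adjusted p = 0.0172, exact test). Within 200 bp the miRNA call (0.714%, odds ratio 4.99, adjusted p = 0.213, exact test) and the piRNA call (0%, adjusted p = 0.191) were lost as well. Without replicate 1 the miRNA share was 3.57% (adjusted p = 0.000240, exact test).

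The next-strongest candidates also lay often near such genes. In the next 140 candidates, a background chosen after seeing the data, 17.1% were near a tRNA gene, 7.86% near a snoRNA gene and 32.9% near an ncRNA gene. Against them the rRNA genes stood at 6 to 0 (exact test, p = 0.0296, adjusted p = 0.118), the snoRNA excess did not pass (odds ratio 2.07, exact test, p = 0.0897, adjusted p = 0.239), the tRNA share was 14.3% (odds ratio 0.806, adjusted p = 0.830), and the ncRNA share was lower in the final peaks (odds ratio 0.423, adjusted p = 0.0286). As 18 of the final peaks but 1 of the next 140 are mitochondrial, the nuclear peaks were also compared with the next 122 nuclear candidates, again a choice made after seeing the data. The tRNA share was then 6.56% against 16.4% (odds ratio 0.358, exact test, p = 0.0257), the snoRNA share 17.2% against 7.38% (odds ratio 2.61, p = 0.0306) and the ncRNA share 19.7% against 32.8% (odds ratio 0.502, p = 0.0286). None passed the adjustment over 8 biotypes (adjusted p = 0.0817 for each of the 3, exact test).

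The final peaks were unevenly spread over the chromosomes (permutation chi-square, p = 1e-05, the smallest that 100000 draws can give), mainly because 18 of the 19 mitochondrial peaks in the comparison were final, where 0.0887 were expected. Among the 122 nuclear peaks, an alternative chosen after seeing the data, the spread also passed the permutation test (p = 0.0213). Chromosome III held 28 against 17.8 expected and chromosome I 24 against 19.3. Chromosome II held 13 against 19.4, chromosome IV 13 against 18.9, chromosome V 17 against 23.2, and X 27 against 23.4.

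Of the 24 gene lists, ribosomal proteins alone passed. Of its 51 members near a candidate, 4 were nearest to a final peak, against 0.493 expected: rps-28 (signal 32.9), rpl-35 (29.1), rpl-3 (20.9) and rpl-14 (20.8) (odds ratio 9.07, Fisher's exact test, two-sided, p = 0.00144, adjusted p = 0.0346). This call was lost with either replicate alone, with 2 members near a top peak without replicate 1 (odds ratio 4.27) and 1 without replicate 2 (odds ratio 1.61; adjusted p = 1 in both, exact test). Among the 70 stronger final peaks it was lost at an odds ratio of 8.51, with fewer peaks (2 members, adjusted p = 0.630, exact test), and when every gene within 1000 bp counted it was lost at 5.96 (5 members, adjusted p = 0.0529). Respiratory chain genes cox-5B (20.8) and cox-5A (20.6) made 2 of 19 members, with an exact test p of 0.0142 that did not pass adjustment (adjusted p = 0.170). The mitochondrial genes nearest to final peaks, such as ND5 and COX3, were not in this list.

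Lists tied to the textbook role of NHR-76 had 0 or 1 members at final peaks, but 1.35 or fewer were expected for each, so none could show a deficit. Of 79 lipid metabolism genes near a candidate, 0 were near a final peak, where 0.763 were expected. Intestine genes gave 0 of 14 (0.135 expected) and vitellogenins 0 of 1 (0.00966 expected). Cytochrome P450 and detoxification gave 0 of 84 (0.812 expected), and serotonin and octopamine signalling gave 0 of 7 (0.0676 expected). Nuclear hormone receptors gave 1 of 140, nhr-192 (20.5), where 1.35 were expected.

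Translation factors gave 1 of 22 (iff-2, 23.6), core histones 1 of 29 (his-67, 22.6), heat shock and chaperones 1 of 38 (dnj-29) and cell cycle 1 of 40 (cdk-9, 24.6). Proteasome, vacuolar ATPase, splicing factors, hypodermis and cuticle, body wall muscle, pharynx, neurons, germline and maternal, homeobox and T-box, bHLH and GATA regulators, cytoskeleton, and Wnt and Notch signalling had 0 members near a final peak. At an unadjusted p under 0.05, 2 of the 24 lists passed Fisher's exact test.

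Whether known binding sites lay under the peaks was asked with 17 motifs. The half-site AGGTCA, bound by many nuclear receptors, was within 100 bp of the summit in 4 final peaks (2.86%, interval 0.784% to 7.15%) against 6.17% of 697 matched candidates (odds ratio 0.447, Fisher's exact test, two-sided, p = 0.158, adjusted p = 0.383 over 17 motifs). Its variant AAGTCA was in 5 (3.57% against 7.60%, exact test, p = 0.101, adjusted p = 0.342). The extended GATA site TGATAA, bound by the GATA factors of the intestine, was in 13 (9.29% against 9.18%, exact test, p = 1, adjusted p = 1). None of these shares differed past the threshold, but against unmatched candidates the share with TGATAA was lower in the final peaks (odds ratio 0.504, exact test, adjusted p = 0.0408).

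The B box of tRNA genes, an internal promoter element of RNA polymerase III, was the 1 motif of 17 that passed, in 10 final peaks (7.14%, interval 3.48% to 12.7%) against 1.15% (odds ratio 6.62, exact test, p = 0.000166, adjusted p = 0.00283). Of the 10, 6 were near an annotated tRNA gene and 3 near a snoRNA gene. The call was lost without replicate 2, where the odds ratio fell to 1.77 (2.86%, adjusted p = 0.580, exact test). Among the 70 stronger peaks it was lost at an odds ratio of 10.5, in fewer peaks (5.71%, adjusted p = 0.140, exact test). Without mitochondrial peaks, a choice made after seeing the data, 2 more motifs passed, the tRNA A box (12.3% against 4.43%, adjusted p = 0.0171, exact test) and a GAGA repeat (35.2% against 23%, adjusted p = 0.0329, exact tests). The background was not matched on signal, and motifs were not compared with the next-strongest candidates. Of the next 122 nuclear candidates, 16.4% were near a tRNA gene, against 6.56% of the nuclear final peaks.

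The loci of the transgene and of atgl-1 were looked at directly, with 2 kb on each side. The strain carries an nhr-76 transgene with an unc-119 rescue, so nhr-76 and unc-119 have extra copies. The samples were mixed-stage embryos, so the intestine was not measured on its own. None of nhr-76, unc-119 and atgl-1 had a final peak. At nhr-76 (chromosome IV, 627537 to 633963) the strongest of 4 pooled candidates had a signal of 9.68 and ranked 1193 of 30000, at 635477 to 635816. At unc-119 (chromosome III, 10902641 to 10908935), which is mutant in this strain, the strongest of 3 candidates ranked 17006. At atgl-1 (chromosome III, 6415772 to 6419459) the strongest of 2 candidates ranked 6006 with a signal of 6.18, replicate 1 listed 0 peaks, and the strongest of 3 in replicate 2 ranked 7946 with a signal of 5.02. Candidates per kb placed nhr-76 at percentile 65.2 of all protein-coding genes, unc-119 at 49.7 and atgl-1 at 46.3.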

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

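Alternatives without mitochondrial peaks, without tRNA and snoRNA peaks, without mitochondrial peaks and 1 replicate, against the next nuclear candidates, against the next candidates in the noncoding test, and with 10 biotypes were chosen after seeing the data; the others were planned. The number of final peaks ran from 122 to 145, and the chromosome test passed under every alternative run. The promoter share passed in 9 of 11 alternatives and not against the next candidates (57.1%) or the next nuclear candidates (55.7%). Support by both replicates was 65.7% among the 70 stronger peaks, 51.4% with the top 280 peaks, and 26.2% without mitochondrial peaks. Rank agreement fell to 0.28 with column 9, where 3188 replicate 1 peaks and 716 replicate 2 peaks tie at the highest value. The number of gene lists called was 0 among the stronger peaks and 0 with every gene within 1000 bp, and 0 to 0 over the replicates left out. The number of noncoding biotypes called was 3 among the stronger peaks, 1 against the next candidates, 0 against the next nuclear candidates, 2 on nuclear peaks without replicate 2 (5 without replicate 1), and 3 to 6 over the replicates left out. Against the next candidates the tRNA (14.3%), miRNA (2.14%) and ncRNA (17.1%) shares reversed, as did tRNA (6.56%) and ncRNA (19.7%) against the next nuclear candidates, and the rRNA share was 0% without mitochondrial peaks, with both replicates or without replicate 1. The number of motifs called was 0 among the stronger peaks, 3 without mitochondrial peaks, 2 with 50 bp windows, 7 against unmatched candidates, and 0 to 3 over the replicates left out. The half-site, at 4.29% to 5.71% over the replicates left out, turned without replicate 2, and the GATA site turned at 10% to 10% over the replicates left out, 6.56% without mitochondrial peaks, 2.86% with 50 bp windows and 9.29% against unmatched candidates, where its lower share passed. The smaller sets have less power by construction, and otherwise the cause was not tested. Replicate support has no value without a replicate. No paired analysis was possible because there is 1 group. Read depth is unknown, so its limit on these lists could not be given.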

Other observations

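Tests of mitochondrial summits and of tRNA and snoRNA peaks taken separately were chosen after the results were seen, as was the search for sequence words itself, and the rule that leaves the mitochondrial test open was set after its value was seen.

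Beyond the fixed motifs, 24 of the 122 nuclear final peaks shared the word GCCGCAC (GTGCGGC on the other strand) within 50 bp of the summit, 19.7% against 1.64% of 610 candidates matched on promoter class and GC content. The word led 5128 words of 7 bases, of which 66 passed Fisher's exact test with Benjamini-Hochberg adjustment (adjusted p = 4.39e-09), and it had first been noticed in a search of words of 6 to 8 bases against unmatched candidates. It was under 9 of the 13 nuclear peaks among the 25 strongest: atx-2, ears-2, idhg-1, dnj-29, C46F11.4, spe-48, K05C4.2, tre-1 and ccdc-47. Weaker peaks with the word included erfa-3, rps-28, gly-13, haf-6, mtss-1, uba-5, krr-1, cdk-9 and drr-2, all named after their values were seen. Of the 24 peaks, 22 were within 500 bp of a protein-coding 5′ end and 0 near a tRNA or snoRNA gene, against 29 of the 98 without the word (Fisher's exact test, p = 9.32e-04). Of those 29, 9 lay within 500 bp of a protein-coding 5′ end, so this contrast was not separated from location. The word was also picked from these same peaks. A further word, TTGCAA, was under 26 nuclear peaks (21.3% against 3.61%), 14 of which also had the first, and in a pairing picked by eye 6 peaks had GTGCGGC followed by TTGCAA after a gap of 4 bases.

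GC content and 1 replicate alone were weighed for these words. Among held-out candidates, the nuclear ones ranked below the final peaks down to rank 1000, GCCGCAC was in 2.10% against 0.980% of lower candidates matched on GC content and promoter class (odds ratio 2.17, interval 1.17 to 3.87), which argues against GC content as the whole cause. The enrichment there was far below the 14.6 in the final peaks, and some of these candidates had been in the background of the search. The odds ratio was 8.70 (interval 3.62 to 22) in the top nuclear peaks of replicate 1. It was 14.9 (6.71 to 35.8) in those of replicate 2, so peaks with the word ranked high in each replicate. Most of these peaks with the word are also final peaks, from which the word was picked, so this enrichment was largely built in. They are no independent test of the word itself. Outside the final set the word was in 2 of 88 top peaks of replicate 1 (odds ratio 1.98, interval 0.186 to 12.4). In replicate 2 it was in 2 of 38 (odds ratio 5.17, interval 0.364 to 73.4). Both intervals include 1, so beyond the final peaks the test cannot decide on 1 replicate alone. A sequence element at these promoters is a hypothesis, finer base composition such as CpG content was not matched, and without an untagged or other-factor control no link to NHR-76 was tested.

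Mitochondrial peaks covered 40.5% of the mitochondrial genome, at 1.30 final peaks per kb against 0.00122 in the nuclear chromosomes. The rotation test assumed that an even excess of mitochondrial DNA in both libraries would place summits independently in each, which was not checked. Of 25 replicate 1 summits, 12 lay within 100 bp of a replicate 2 summit, against a median of 9 over all rotations, and a share of 0.0829 of rotations gave as many. By summit position alone, an even excess and positions shared between replicates cannot be told apart, since the summits are dense and few. Signal was not part of this test. The ND5 peak ranked first in both replicates, but only 9 of the 18 mitochondrial final peaks had a listed summit within 100 bp in both. No biological explanation was tested.

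For tRNA and snoRNA peaks, reads shared between repeated copies were weighed as a source. Under the 29 nuclear peaks of both kinds the median share of 31-base words with another exact copy in the genome was 0%, but 21 of them are snoRNA peaks, so this median does not speak for the tRNA peaks. Under the 21 snoRNA peaks alone the median was 0%, as under the 93 other nuclear peaks, which argues against shared reads there. Under the 8 tRNA peaks it was 16.5% (quartiles 15.1% to 18.8%), between the bounds set. The share was taken over the whole peak, of which a tRNA gene fills only a small part. Even a fully repeated tRNA gene could therefore stay below the upper bound. The test cannot decide for these peaks, and shared reads stay open for them. No biological explanation was tested.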
